A study of Drosophila melanogaster with 15 samples.

How the data were processed

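RNA from brains and imaginal discs of wandering larvae of the 3rd instar was measured on 15 Affymetrix Drosophila Genome 2.0 arrays, a single-colour platform with biotin-labelled cRNA. Per the labels, tissue of 10 larvae was pooled for each sample, the flies were raised at 25 °C, total RNA was extracted with Trizol, and 500 ng went into the labelling reaction of a 3' in vitro transcription kit. The samples form 5 groups of 3. Mutants of DSas-4 and of DSas-6 are described by the submitters as lacking centrosomes, and a strain overexpressing Sak, called SakOE here, as having too many. The others are the wild-type strains w67 and OregonR. The labels call the samples of a group biological replicates, and groups and replicate numbers were taken from the sample titles and genotypes.

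Per the submitters' processing notes, the authors used GCRMA, which corrects probe intensities for background and combines the probes of a probe set into 1 value, and limma; versions were not given in the sources used here. The deposited values were taken as log2 expression from that note and from their range, 2.174 to 15, since the scale itself is not stated. The lowest value was the same in all arrays of a group, but took 4 different values over the 15 arrays, with DSas-4 and w67 sharing 1 of them. Exact ties of the tested genes (tolerance 1e-09) were found 411 times between arrays that share the lowest value and 0 times between arrays that do not. The values thus look as if 4 separate normalization runs had been used, in which case DSas-4 against w67 is the contrast that lies within 1 run. In every other contrast the run and the group cannot be told apart. For that reason the genes called against both wild types were also counted after centring each array on its median and after quantile normalization of the deposited values, and single contrasts were given after at least 1 of these where the share of higher genes moved by over 10 points or turned.

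Each array held values for 18952 probe sets. The platform's annotation table gave 1 gene symbol for 13647 of them, several for 402 and none for 4903. There, 13544 of the first kind were found by Entrez number in the RefSeq gene table of Drosophila melanogaster Release 6, and no symbol had to be updated. In total 11982 genes had a probe set of their own. That table was also used for the chromosome arm of each gene. No genome was used here, so no coordinates are given. Probe sets with several symbols or none entered no comparison of genes and were tested apart. No single-symbol probe set was matched to w (white), which is not analysed here.

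Depth has no counterpart on arrays, so the number of arrays limits the precision. Between 44.4% and 44.8% of the probe sets of an array reached a log2 value of 4, and 32.6% to 34.3% lay at the lowest value. Replicates correlated at r of at least 0.988 over the tested genes, and the median SD of a gene within a group was between 0.07 and 0.09.

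A probe set was kept when it reached 4 in at least 3 arrays, and each gene was represented by its probe set with the highest mean, which left 6973 genes. A model with 1 mean per group was fitted to all 15 arrays with limma 3.58.1 (lmFit and eBayes) in R 4.3.3, so that every group shares 1 estimate of the spread. All tests were two-sided, p-values were adjusted by the Benjamini-Hochberg method within each contrast, and the threshold was an adjusted p of 0.05. A gene was called in a mutant strain when it passed against w67 and against OregonR in the same direction; rose and fell refer to such calls. Fold changes against both wild types are those of the smaller of the 2 differences. Where a gene stayed under 4 on all arrays of a group, its level there is open, and the fold was computed against the filter level as "at least N-fold", or not given where the mean of the other group was also under 4.

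Overlaps of gene lists between strains share the wild-type arrays as controls. They were set against 100 simulations of unchanged groups sharing those controls, against the overlap of independent lists, and against splits in which 1 strain was compared with w67 and the other with OregonR. In all, 32 gene lists for centrosomes, cell division, stress, metabolism, cell types and other tissues were fixed before the data were examined. Lists with at least 5 measured members were tested with limma's camera at a preset correlation of 0.01, adjusted over the 27 lists tested; camera with an estimated correlation and fry were alternatives. Called genes on chromosome 3 and elsewhere were compared with Fisher's exact test, with 95% confidence intervals.

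Genes named below follow a rule fixed with the lists: Sas-4, Sas-6, SAK and w always; for each mutant strain the 10 called genes with the largest smaller difference in each direction; up to 10 shared genes of the centrosome-loss mutants in each direction; the 5 largest in each direction for w67 against OregonR and for SakOE against the loss mutants; and of each list up to 4 called members, or up to 2 of the highest mean level where none was called. Of the 185 genes this gave, 27 lay on probe sets that may also match other transcripts. Genes named outside the rule are said to be so.

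The steps were tested on simulated data with 6973 genes and known changes. Of 100 genes changed by 0.5 log2 units, 81 were called in DSas-4, 75 in DSas-6 and 82 in SakOE; of 100 changed by 1 unit, 97, 96 and 92. Called without a change were 2, 2 and 1 genes. For SakOE against the loss mutants, 359 of 391 changed genes were recovered, and w67 against OregonR gave 0 calls with no change simulated. The 1 list moved in the simulation was found, and 0 of the others were called. The simulated genes varied independently, with no difference between the wild types and no offset between normalization runs. The false calls counted here therefore do not cover correlated lists or such offsets. Alternatives covered the filter, the scaling, the treatment of several probe sets, variance trend and array weights, the replicate number as a block, a minimum fold change, the arrays in the fit, and each array left out in turn.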

Results

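Expression was measured in brains and imaginal discs, the dividing tissues of the late larva, from flies labelled as lacking centrosomes (DSas-4 and DSas-6) or having too many (SakOE) and from the wild types w67 and OregonR, with 3 arrays per strain. The design compared each altered strain with both wild types. The 15 arrays had similar ranges, from 2.174 to 15 on the log2 scale, and the group medians of the tested genes lay between 8.71 and 8.84. The 6973 genes tested are those with a probe set of their own and a log2 value of at least 4 in at least 3 arrays. Errors are SD with n = 3 arrays unless stated otherwise.

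The targeted genes come first, because they check the labels. Sas-4, which builds the centriole wall and recruits pericentriolar material, fell in the DSas-4 arrays, to 4.84 ± 0.23 from 7.62 ± 0.17 in w67 and 7.68 ± 0.09 in OregonR. The Sas-4 difference was -2.77 against w67 (limma, adjusted p = 2.25e-08) and -2.84 against OregonR (adjusted p = 1.64e-08). All 3 arrays, from 4.66 to 5.10, lay below every wild-type array. Sas-6, the protein of the centriolar cartwheel, fell in the DSas-6 arrays to 3.21 ± 0.09 from 7.73 ± 0.09 in w67 and 7.65 ± 0.05 in OregonR, at least 12.6-fold (limma, adjusted p = 1.97e-11 and 2.46e-11). SAK, the kinase that starts centriole duplication, was not higher in the arrays labelled SakOE, at 7.53 ± 0.04 against 7.84 ± 0.11 in w67 and 7.51 ± 0.11 in OregonR. Its difference from w67 was -0.30 and passed the threshold, but was -0.18 and no longer past it after each array was centred on its median. It also missed the threshold when SakOE replicate 2 (-0.29), SakOE replicate 3 (-0.30), w67 replicate 1 (-0.27) or w67 replicate 2 (-0.28) was left out. The SAK difference from OregonR was 0.03 and did not pass. Each of these genes has a single probe set, and whether that of SAK lies in the part carried by the transgene is not known here, so the label SakOE is neither borne out nor contradicted by it. One array control probe set for vector sequence, singled out after its values were seen, stood at 8.62 ± 0.11 in the arrays labelled SakOE and at the lowest value in the other 12 arrays.

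**Figure D1:**
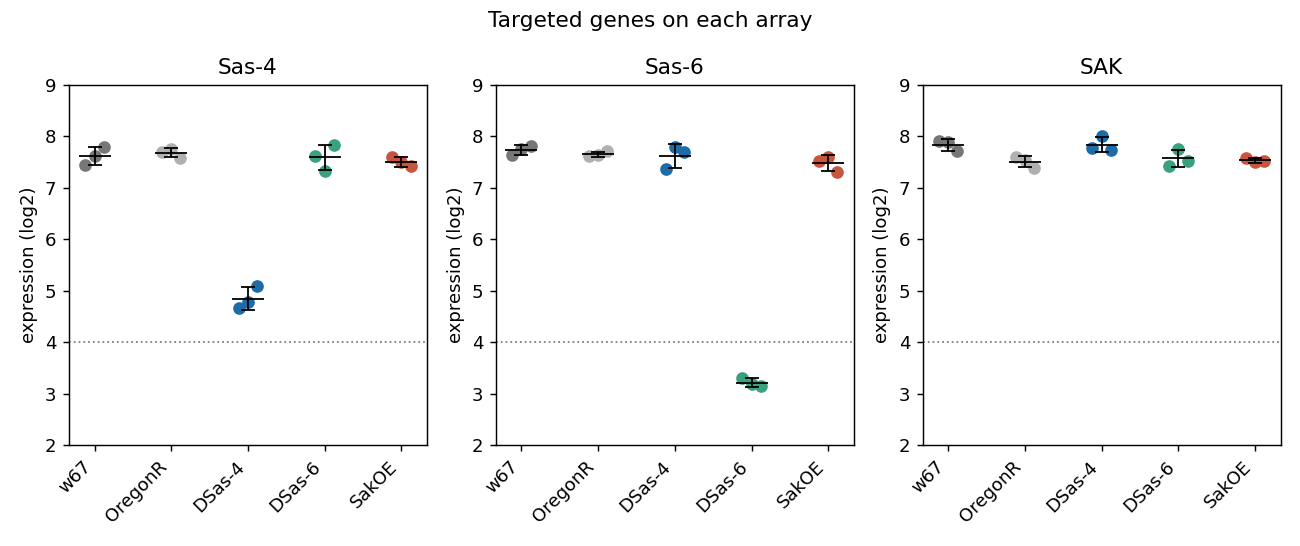
Expression (log2) of Sas-4, Sas-6 and SAK on each of the 15 arrays, with 1 point per array, the mean of each strain as a horizontal bar, the SD as an error bar and the level of 4 used in the filter as a dotted line. Sas-4 was 4.84 in the DSas-4 arrays and Sas-6 was 3.21 in the DSas-6 arrays, below every wild-type array, while SAK in the arrays labelled SakOE (7.53) lay near OregonR (7.51).

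What the loss of centrosomes changes was asked first with DSas-4: 230 genes differed from both wild types, 123 higher and 107 lower. The split turned after median centring (113 higher, 126 lower) and after quantile normalization (108 higher, 136 lower). Hsc70-2, a member of the Hsp70 chaperone family, stood at 9.41 ± 0.07 and was under 4 on all 3 arrays of each wild type, at least 42.5-fold higher. The uncharacterised genes CG31157 (at least 8.16-fold) and CG31287 (at least 6.38-fold), the thiol reductase gene GILT3 (at least 7.80-fold) and Dred (at least 3.97-fold, on a probe set that may match other transcripts) rose from levels under 4. Among genes measured on both sides, Oat, the ornithine aminotransferase, rose 4.69-fold, CG14687 4.35-fold and CG7966 3.56-fold. The midkine-like growth factor gene miple1 rose 3.50-fold and the glycosyltransferase gene Ugt302K1 3.45-fold.

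The largest decreases in DSas-4 mutants were in Ir76a, an ionotropic chemoreceptor gene (17.9-fold, to 4.69 ± 0.79, probe set possibly shared), Cyp4g1, the cytochrome P450 of oenocyte hydrocarbon synthesis (12.4-fold, to 4.19 ± 1.67), and CG6912 (10.2-fold, to 5.76 ± 1.14). Sas-4 itself (6.83-fold), CG7768 (3.48-fold), the potassium channel gene Shal (at least 2.12-fold), the catalase gene Irc (3.03-fold), the histone acetyltransferase adaptor Ada2a (2.87-fold, SD 0.69), lncRNA:CR43242 (3.12-fold) and lncRNA:CR32027 (2.83-fold) completed the 10 largest. All 3 mutant arrays lay beyond all 6 wild-type arrays for these 20 genes, and for 226 of the 230 called genes. By chance 1.19% of unselected genes would do so in 1 direction, a share that does not apply as a test to genes selected for differing from both wild types. The adjusted p of the 20 genes (limma) was at most 0.00825.

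Few members of the fixed lists changed in DSas-4 mutants, as did few of all tested genes (3.30% called). A low count therefore does not by itself set a list apart. Of 21 measured genes of detoxification and oxidative stress, the cytochrome P450 gene Cyp4e2 (2.20-fold) and the glutathione transferases GstD3 (2.08-fold) and GstD1 (1.45-fold) rose and Cyp4p1 fell 2.28-fold. Of 19 centriole and pericentriolar material genes, Sas-4 and ana2, a duplication factor (1.34-fold), fell. In DNA replication (26 genes) RPA1, the large subunit of replication protein A, rose 1.45-fold and Psf1 of the GINS complex fell 1.41-fold. Single members changed in 7 further lists. There, scaf of the JNK, JAK/STAT and stress targets rose 1.61-fold (17 genes, probe set possibly shared). The synapsin gene Syn rose 1.35-fold (20 neuronal genes) and the lipophorin gene apolpp rose 1.21-fold (13 fat body genes, not after quantile normalization). The scavenger receptor gene Sr-CI rose at least 1.53-fold (16 haemocyte and lymph gland genes). The nuclear receptor gene Eip78C fell 2.38-fold (20 ecdysone response genes). The glial transcription factor repo fell 1.25-fold (17 glial genes), and nvd of ecdysone synthesis fell 1.77-fold (10 ring gland genes). Of these calls, ana2 (-0.26), apolpp (0.29), Sr-CI (0.48) and nvd (-0.52) were lost without DSas-4 replicate 1, and Syn (0.36) without replicate 2. Each of them was also lost without at least 1 w67 array, without at least 1 OregonR array and with no filter on dim probe sets. The Syn call was also lost with the replicate number as a block (0.44). No measured member was called in the lists for spindle and motors (27 genes), kinetochore and checkpoint (26), cell cycle regulators (20), DNA damage response (20), apoptosis (16) and heat shock and chaperones (11). The same held for humoral immunity (4), ribosomal proteins (26), ribosome biogenesis (23), proteasome (28), glycolysis (14), oxidative phosphorylation (34), neuroblasts (17), eye disc (21), wing, leg and haltere disc (28), cilium (6), muscle (6), salivary gland (2), cuticle and trachea (5), testis (4) and dosage compensation and sex determination (4). Of their 342 members, 23 had an unadjusted limma p under 0.05 against both wild types in the same direction. Among the highest expressed of them, betaTub56D stood at 14.47 ± 0.05 against 14.42 ± 0.01 in w67 and 14.41 ± 0.03 in OregonR, and the checkpoint gene Bub3 at 12.51 ± 0.04 against 12.50 ± 0.06 and 12.42 ± 0.03. The gut list had 0 members past the filter.

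As whole lists, 2 stood above the other genes in DSas-4 mutants in the camera test. The 17 JNK, JAK/STAT and stress genes had a median difference of 0.13 against w67 and 0.31 against OregonR (adjusted p = 0.0109 and 0.0056; adjusted p = 0.159 and 0.0936 with an estimated correlation). The 16 haemocyte and lymph gland genes had medians of 0.50 and 1.03 (adjusted p = 0.00111 and 0.00197; adjusted p = 0.938 and 0.946 with an estimated correlation). The mean of the haemocyte list was 8.59 in DSas-4 replicate 1, against 7.62 and 7.55 in replicates 2 and 3, and the list was no longer called without replicate 1. With fry the haemocyte list was not called (adjusted p = 0.285 against w67), while the JNK, JAK/STAT and stress list and the detoxification list were. Adjusted over the list alone, 5 haemocyte genes rose and 1 salivary gland gene rose, and the counts of the other lists were as over all genes.

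**Figure D2:**
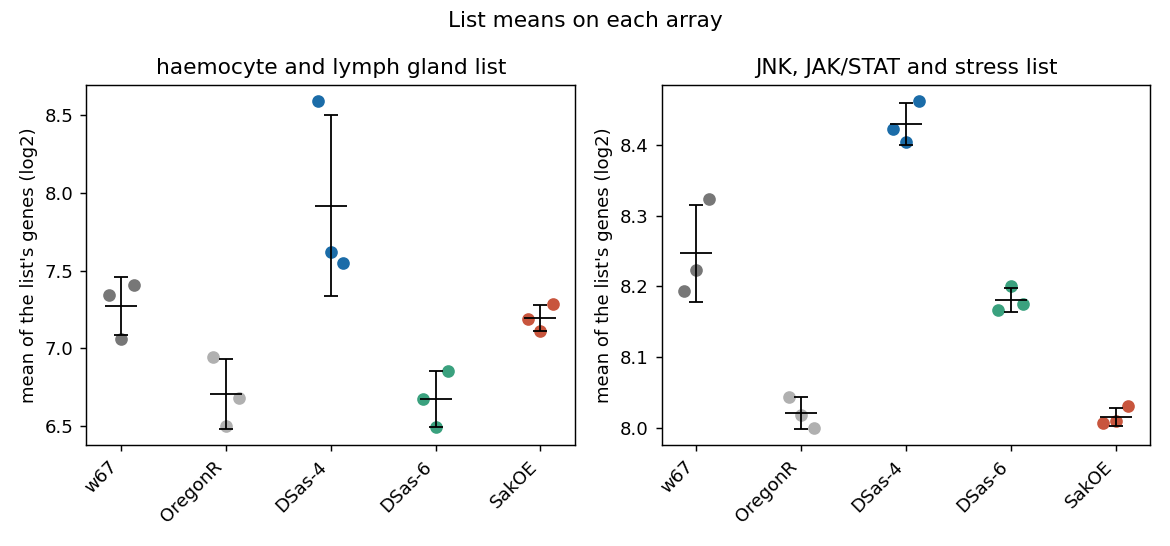
Mean log2 expression of the haemocyte and lymph gland list (16 genes) and of the JNK, JAK/STAT and stress list (17 genes) on each array, with 1 point per array, strain means as horizontal bars and the SD as error bars; the vertical axes do not start at 0 and differ between panels. DSas-4 replicate 1 stands at 8.59 in the haemocyte list, above all other arrays.

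The limma counts for DSas-4 were 321 genes against w67 (137 higher, 184 lower) and 1736 against OregonR (1427 higher, 309 lower); after median centring the latter were 601 higher and 650 lower. The count against w67 was 204 without w67 replicate 2, and that against OregonR was 1111 both without DSas-4 replicate 3 and without OregonR replicate 3. Of the 230 genes called against both, 26 also differed between the wild types, and 44 differed by at least 1 log2 unit.

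The same question for DSas-6, the other mutant without centrosomes, gave 429 called genes, 149 higher and 280 lower, and most differences were small, with a median size of 0.35 and 12 genes at 1 log2 unit or more. The genes that rose were led by CG15831 (at least 1.96-fold), the nuclear import receptor gene Tnpo (2.84-fold, probe set possibly shared), Tet, which encodes a methylcytosine dioxygenase homologue (2.79-fold), dpy, which encodes a giant protein of the apical extracellular matrix (2.50-fold), the axon guidance gene Sema1a (2.32-fold), the Wingless-binding proteoglycan gene Cow (1.98-fold) and the splicing regulator sm (1.78-fold). CG13068 (1.79-fold), Alg-2 (at least 1.27-fold) and Dyro (at least 1.64-fold) completed the 10. In DSas-6 replicate 3, Tet (7.71), Sema1a (7.24), Cow (5.24) and sm (9.65) stood well below replicates 1 and 2. Those were 8.54 and 8.90 for Tet, 8.16 and 8.23 for Sema1a, 6.61 and 6.17 for Cow, and 10.58 and 10.46 for sm. The other genes of the 10 varied less between replicates, and Tnpo was highest in replicate 3.

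Among decreases, Sas-6 was followed by CG18213 (to 3.99 ± 0.09), CG31495 and GILT3, the lysine degradation gene LKRSDH (at least 1.96-fold), CG30379 (2.01-fold), the neprilysin gene Nep1 (1.96-fold, probe set possibly shared). Next were CG7650 (at least 1.32-fold), CG30403 (at least 1.14-fold) and the tachykinin receptor gene TkR86C (at least 1.04-fold). No fold is given for GILT3, under 4 on all arrays of DSas-6 and both wild types, nor for CG31495, near 4 in the wild types. The 20 genes had an adjusted p (limma) of at most 0.0342, and for 19 of them all 3 mutant arrays lay beyond all 6 wild-type arrays, the exception being Cow. GILT3 was not called after quantile normalization, Cow was not called without DSas-6 replicate 1 or 2 or w67 replicate 2 or 3, and sm not without DSas-6 replicate 1 or 2 or any 1 OregonR array.

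In the fixed lists, DSas-6 mutants showed changes of single genes spread over 18 lists, with 6.15% of all tested genes called. Of 21 eye disc genes, ey, the eye selector gene (1.26-fold), dan (1.24-fold) and sev (1.29-fold, not after either rescaling) fell. Of 17 neuroblast genes, the fate determinants brat (1.65-fold, probe set possibly shared) and pros (1.41-fold) rose. The vesicular transporter gene Vmat, a member of both the neuronal and the glial list, rose 1.53-fold. The temporal factor chinmo rose 1.27-fold, the hexokinase gene Hex-A 1.63-fold, Cyp4e2 1.59-fold, zfh2 of the wing, leg and haltere list 1.49-fold and the sex determination gene Sxl 1.46-fold (probe set possibly shared). With the mean of all probe sets of a gene, the calls of Vmat (0.53) and Sxl (0.23) were lost. Oseg4 of intraflagellar transport fell 1.28-fold, the RNA polymerase I subunit Polr1H 1.44-fold and ND-42 of respiratory complex I 1.17-fold. Of 19 centriole genes, Sas-6 and Cp110 (1.16-fold, probe set possibly shared, not after quantile normalization) fell. The remaining calls of list members were lost under rescaling: EcR (probe set possibly shared) and sls rose and pnr and ush fell in the deposited values and were called after neither median centring nor quantile normalization. Corp (dim, no fold given) was lost in the same way, and E2f2 fell 1.10-fold but not after median centring. Without DSas-6 replicate 1 the calls of pros (0.37), Vmat (0.46), Cyp4e2 (0.58), chinmo (0.29), zfh2 (0.50), E2f2, Corp, EcR, sev, pnr, sls and ush were lost, and without replicate 2 that of dan (-0.24). Each of these calls was also lost without at least 1 wild-type array.

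No member was called in DSas-6 mutants in the lists for spindle and motors, kinetochore and checkpoint, DNA replication, apoptosis, heat shock, humoral immunity, ribosomal proteins, proteasome, fat body, salivary gland, cuticle and trachea, testis and ring gland. Of the 198 members of these 13 lists, 12 had an unadjusted limma p under 0.05 against both wild types in the same direction. The replication clamp gene PCNA stood at 12.26 ± 0.06 against 12.20 ± 0.08 in w67 and 12.28 ± 0.04 in OregonR. No list was called with camera (2 at an unadjusted p under 0.05 against both, ribosomal proteins and neurons), nor with an estimated correlation, and 1, centriole and pericentriolar material, was lower with fry. That list holds the mutated gene Sas-6 itself and was not tested without it. Adjusted over the list alone, 2 JNK and stress genes rose, 0 ecdysone response genes were called and 5 eye disc genes fell. In that count 2 disc patterning genes rose and 1 fell, and 1 muscle gene rose and 1 fell; the other lists had the counts given over all genes.

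Some array controls outside the tested genes also stood higher in DSas-6, untested. The 6 probe sets of the spike-in dap, a bacterial RNA added in labelling, averaged 8.89 ± 0.11 against 8.04 ± 0.59 in w67 and 8.18 ± 0.34 in OregonR. Those of 18S ribosomal RNA averaged 11.3 ± 0.25 against 10.2 ± 0.98 and 10.2 ± 0.40, though the highest w67 array (11.02) reached the lowest of DSas-6 (11.01). The hybridization controls bioB, bioC, bioD and cre did not stand above both wild types, with bioB at 7.46 ± 0.11 against 7.51 ± 0.29 and 7.65 ± 0.12. Against w67 alone, 1495 genes passed (213 higher, 1282 lower; 434 and 565 after median centring) and against OregonR 971 (548 higher, 423 lower; 464 and 555 after median centring). The count against w67 was 951 without DSas-6 replicate 1, 878 without DSas-6 replicate 2 and 836 without w67 replicate 3, and that against OregonR was 613 without DSas-6 replicate 1. Rescaling moved the split of the genes called against both, from 34.7% higher to 43.2% after median centring (188 higher, 247 lower) and 49.6% after quantile normalization (211 higher, 214 lower), with 346 and 314 of the 429 called there too. The count was 253 without DSas-6 replicate 1 and 275 without replicate 2.

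What too many centrosomes change was the question put to the arrays labelled SakOE, which had 746 genes called against both wild types, 241 higher and 505 lower. CG32055, at the lowest value or close to it in both wild types, rose to 7.81 ± 0.73, at least 14-fold. CG14687 rose 7.37-fold, the tubulin gene alphaTub85E 5.65-fold, Oat 4.85-fold, CG5618 4.18-fold, CG14662 at least 4.63-fold, Gabat, the GABA transaminase, at least 3.69-fold (probe set possibly shared), Dred at least 3.41-fold, dsx-c73A at least 2.70-fold and CG13032 at least 2.65-fold.

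The decreases in the arrays labelled SakOE were as large. CG7900 fell at least 13.7-fold, CG6912 23.9-fold (to 4.52 ± 1.45), CG11999 18.8-fold (to 5.60 ± 0.19), Cyp4g1 to 3.75 ± 0.43 (from 8.42 ± 0.35 in w67 and 7.82 ± 0.78 in OregonR), CG43085 10.4-fold (to 5.85 ± 1.05), Brf, a subunit of the RNA polymerase III initiation factor, 8.34-fold, and lncRNA:CR32027 5.05-fold. The cuticle protein gene Cpr49Ah (3.01-fold), CG7173 (no fold given) and TkR86C (at least 1.04-fold) completed the 10. For 19 of these 20 genes all 3 arrays lay beyond all 6 wild-type arrays; Cpr49Ah overlapped and was not called without SakOE replicate 2 or 3 or OregonR replicate 1 or 3. The largest adjusted p of the 20 was 0.0177 (limma).

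Over all tested genes the arrays labelled SakOE lay below w67 by a median of -0.12, so smaller changes are given relative to the median of each array. The neuroblast list had 5 of 17 genes lower: svp fell by 1.39 against w67 and by 1.35 against OregonR, pros by 0.74 and 0.83, cas by 1.03 and 0.72, and ase was also called in the deposited values; 4 remained after median centring, without ase. In DNA replication, 8 of 26 genes fell and 2 rose, but 3 and 2 after median centring; PolE1, the catalytic subunit of DNA polymerase epsilon, fell by 0.42 and 0.38, the MCM helicase subunit dpa by 0.25 and 0.31, and RPA1 rose by 0.49 and 0.33. Of 10 ring gland genes, the ecdysone synthesis genes nvd (-1.31 and -1.16) and dib (-1.11 and -0.87) fell, as did sad before centring. Of 11 heat shock and chaperone genes, Gp93 (0.90 and 0.76) and Hsc70-3 (0.69 and 0.51, probe set possibly shared), which encode chaperones of the endoplasmic reticulum, rose.

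Other cell division genes that fell in the arrays labelled SakOE were mus304 (-0.77 and -0.68) and Snm1 of DNA repair, mud (-0.58 and -0.67) and alphaTub84D (probe set possibly shared) of the spindle, Kmn1 (-0.41 and -0.50) and Mps1 of the kinetochore, and Rbf2 (-0.48 and -0.68) of the cell cycle regulators. Of 19 centriole genes, ana3 fell (-0.31 and -0.40, not after quantile normalization), and Cp110 fell in the deposited values but after neither rescaling. The same loss under both rescalings held for Corp, msd5, Orc2, sad, ase and pnr. Single changes were those of Cyp4e2 (0.96 and 1.02), Syn (0.45 and 0.53), the caspase gene Dronc (0.53 and 0.42), Prosalpha4, wrapper, bab2, caup, CG5966 and sage, which rose. Those that fell were ftz-f1 (-0.71 and -0.91), a nuclear receptor gene of the ecdysone response and stress lists, the GABA receptor gene Rdl (-0.71 and -0.59), Ugt302C1, Polr1H, ND-42 (not after median centring), Kap3 and Lpin. In the deposited values, the calls of cas (-0.66), dib (-0.87), Rdl (-0.35), Cyp4e2 (0.69), Syn (0.33), Dronc, ftz-f1, Snm1, bab2, caup, CG5966, msd5, Orc2, ase, pnr and sad were lost without SakOE replicate 3. Each of these calls was also lost without at least 1 wild-type array. The calls of Kap3 (-0.28), Prosalpha4, wrapper and Cp110 were lost without SakOE replicate 2, and that of RPA1 (0.26) without OregonR replicate 2. Those of Kap3, wrapper and Cp110 were also lost without at least 1 wild-type array. With the replicate number as a block, the calls of Rdl (-0.61), Syn (0.33), wrapper and caup were lost. No member was called among ribosomal proteins (26 genes), glycolysis (14), humoral immunity (4), muscle (6), cuticle and trachea (5), haemocytes and lymph gland (16), testis (4) and dosage compensation and sex determination (4), whose 79 members included 4 with an unadjusted limma p under 0.05 against both wild types in the same direction. Enolase (Eno) stood at 12.70 ± 0.07 against 12.76 ± 0.07 in w67 and 12.51 ± 0.04 in OregonR.

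No list was called as a whole with camera in the arrays labelled SakOE (2 at an unadjusted p under 0.05 against both, centriole material and neuroblasts), nor with an estimated correlation. With fry the neuroblast list was lower, and after median centring camera called neuroblasts and ring gland, both lower. With no filter on dim probe sets, camera called 7 lists lower: centriole material, spindle, kinetochore, DNA replication, DNA damage, proteasome and neuroblasts. Without the filter, genes at the lowest value join those a list is compared with. That value was 2.181 in SakOE, 2.1741 in w67 and 2.1799 in OregonR, so these calls can reflect the offset. Adjusted over the list alone, 7 neuroblast genes and 12 replication genes fell (2 replication genes rose), 4 DNA damage genes fell, 1 detoxification gene rose and 2 fell, 1 muscle gene rose and 2 fell, and 0 glial and 0 disc patterning genes were called; the other lists had the counts given over all genes.

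Against w67 alone, 2280 genes passed in the arrays labelled SakOE (319 higher, 1961 lower; 622 and 572 after median centring; 1413 genes without w67 replicate 3), and against OregonR 1269 (591 higher, 678 lower; 664 and 606 after median centring). Rescaling turned the split of the 746 genes called against both, 32.3% of them higher: 363 were higher and 283 lower after median centring (56.2% higher), and 338 and 283 after quantile normalization, with 524 and 517 of the 746 called there too. Both rescalings remove a common shift by construction, so the cause of the excess of lower genes stays open.

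**Figure D3:**
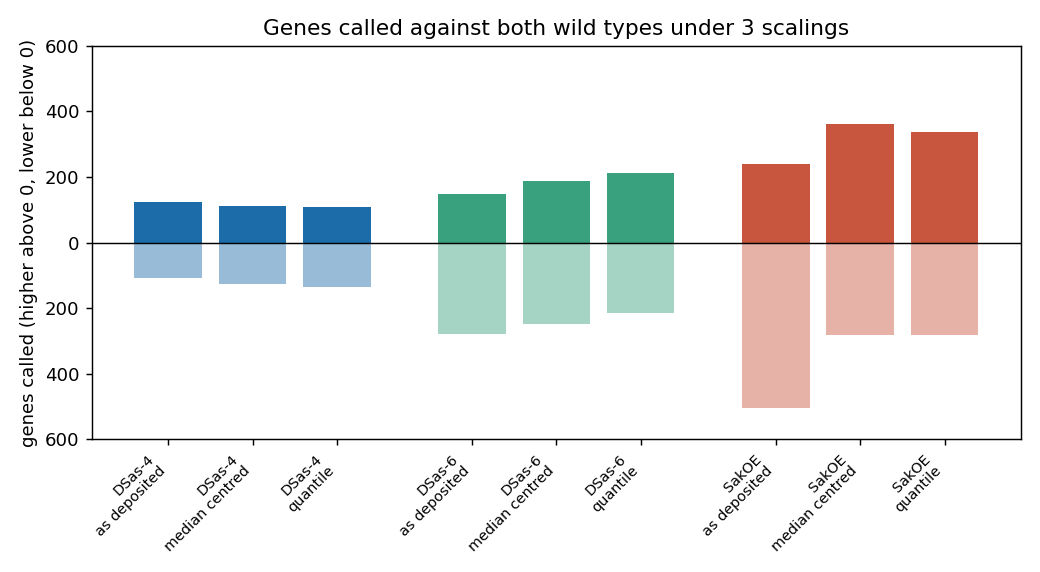
Numbers of genes called against both wild types in each strain, as bars above 0 for higher and below 0 for lower genes, in the deposited values, after centring each array on its median and after quantile normalization. In SakOE the deposited values gave 241 higher and 505 lower genes, and the median-centred values 363 and 283.

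The direct comparison, meant by the design to set too many centrosomes against none, gave 1769 genes between the arrays labelled SakOE and the mean of the DSas-4 and DSas-6 arrays, 425 higher and 1344 lower; after median centring these were 727 and 579, and 1306 in total. CG32055 (7.81 ± 0.73 in SakOE, under 4 on all DSas-4 and DSas-6 arrays), CG13032, CG14662 and Gabat, all likewise under 4 in both mutants, and alphaTub85E (8.70 ± 0.46 against 5.92 ± 0.05 in DSas-4 and 6.37 ± 0.07 in DSas-6) were the 5 largest increases. CG7900 (2.24 ± 0.09 against 7.45 ± 0.11 and 7.82 ± 0.12), CG43085, CG11999, Hsc70-2 and Brf (4.81 ± 0.15 against 8.02 ± 0.16 and 7.46 ± 0.03) were the largest decreases. Hsc70-2 was high in DSas-4 alone (9.41 ± 0.07), at 2.18 in both SakOE and DSas-6, so its place here comes from 1 of the 2 mutants. The largest adjusted p among these 10 genes was 1.46e-06 (limma). The count was 1130 without SakOE replicate 2 and 1100 without replicate 3.

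Whether the 2 ways of losing centrosomes change the same genes was asked next: 15 genes were called in both mutants in the same direction and 11 in opposite directions. Named of the 15 were Set8, a histone methyltransferase gene (1.56-fold in DSas-4, 1.44-fold in DSas-6), CG44085, Cyp4e2, GNBP2 of the recognition of microbial glucans. Also higher were CG7332, Usp10, tay, shi, which encodes the GTPase dynamin, CG3857 and CG12567, while CG14301, CG3726, CG1024 and corn fell. None reached 1 log2 unit in both mutants. The probe sets of Set8, CG44085 and CG3857 may match other transcripts, and CG14301, shi and CG12567 lost the call in 1 of the mutants under a rescaling. With the mean of all probe sets of a gene, CG3857 (0.0154), corn (0) and shi (0.20) lost the shared call. Independent lists of these sizes would share 6.92 genes in the same direction and 7.23 in opposite directions. Unchanged groups with the same controls shared 0.02 on average and at most 1. Such groups have hardly any calls to share, so this is no measure for lists of the real sizes. With split controls, 30 genes went the same way and 38 opposite ways (expected 21.9 and 22.8) with DSas-4 set against w67 and DSas-6 against OregonR, and 92 and 433 (expected 100.4 and 271.8) the other way round, or 79 and 162 after quantile normalization. Over all tested genes the fold changes of the 2 mutants correlated across genes, which are not independent replicates, at r = 0.056 against 0.333 in unchanged groups, with a covariance of 0.00356 against 0.00406. The direct test between the mutants gave 1744 genes, 1400 higher and 344 lower in DSas-4 (853 and 634 after median centring, 728 and 739 after quantile normalization). The overlap was 9 without DSas-6 replicate 1, where Cyp4e2, CG3857, CG7332, CG12567, GNBP2 and shi were not shared; CG14301, corn and CG1024 were not shared without DSas-4 replicate 2.

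How far the wild types differ sets the background: they differed in 1095 genes, 961 higher and 134 lower in w67. CG8245 (7.82 ± 0.44 in OregonR), CR44101 (6.73 ± 0.36) and CG14785 (4.89 ± 0.18) were under 4 on all w67 arrays. The genes path, encoding an amino acid transporter (7.64 ± 0.17 in w67 and 9.70 ± 0.78 in OregonR), and CG31676 (6.42 ± 0.44 and 7.95 ± 0.18) were also lower in w67. Higher in w67 were Lectin-galC1, a galactose-binding lectin gene (5.43 ± 1.21, under 4 in OregonR), CG32572 (6.90 ± 0.05 against 5.21 ± 0.29), the pupal cuticle gene Pcp (5.98 ± 0.17 against 4.52 ± 0.40), CG2233 (5.53 ± 0.14 against 4.09 ± 0.31) and CG6660 (5.81 ± 0.69 against 4.49 ± 0.05), the last of which was called after neither rescaling. Lectin-galC1 missed the threshold without w67 replicate 2 or 3, and CG6660 without any 1 of these or of the OregonR arrays. The largest adjusted p of these 10 was 0.0403 (limma). After median centring 497 genes passed the threshold, 243 higher and 254 lower, and after quantile normalization 538, 249 higher and 289 lower. Both rescalings remove a common shift by construction, so they do not show where the excess came from. The count was 665 and 606 without w67 replicates 2 and 3, and 685 and 680 without OregonR replicates 2 and 3.

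Genes called in DSas-4 mutants lay mostly on chromosome 3, which carries Sas-4 and Sas-6, both on arm 3R. Of the 229 called genes with a known arm, 181 (79.0%) were on chromosome 3, against 44.6% of the genes tested (odds ratio 4.92, 95% interval 3.55 to 6.94, Fisher's exact test, two-sided, p = 3.37e-27, adjusted p = 9.43e-26 over 28 tests). Both arms were enriched (2.173 on 3L, 2.564 on 3R). Hsc70-2, CG31157, CG31287, GILT3, Oat and miple1 are among them. In SakOE, tested after the first 2 results were seen, 458 of 744 called genes were on chromosome 3 (odds ratio 2.165, 1.85 to 2.54, Fisher's exact test, p = 7.52e-23). In DSas-6 mutants 197 of 426 were (odds ratio 1.08, 0.879 to 1.32, Fisher's exact test, p = 0.481). Genes differing between the wild types lay on chromosome 3 less often than the rest (odds ratio 0.702, 0.613 to 0.803). Outside chromosome 3, with its genes left out of the fit, 30 genes were called in DSas-4, 240 in DSas-6 and 274 in SakOE.

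**Figure D4:**
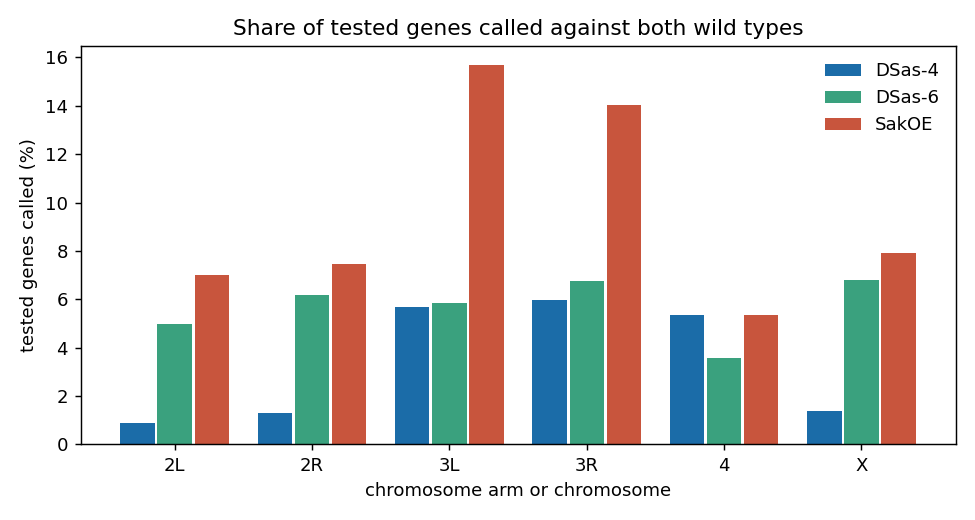
Percentage of the tested genes of each chromosome arm, or of chromosomes 4 and X, that were called against both wild types in each strain, as bars from 0. In DSas-4 mutants 5.69% of genes on 3L and 5.96% on 3R were called, against 0.894% on 2L and 1.29% on 2R.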

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

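Results that stood out from the main comparisons are listed here. The tests on the place of the DSas-4 genes were chosen only after the result was seen, apart from that of strain variants under the probes, which was laid down before it, as were the splits of the arrays.

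The genes called in DSas-4 mutants lay mostly on chromosome 3, with an odds ratio of 4.92 and both arms enriched. An effect of centrosome loss itself was argued against: over the 181 chromosome 3 genes the DSas-6 change was a median 0.0238 of the DSas-4 change (95% interval -0.00482 to 0.0828), with the same sign in 103 of them. Strain variants under the probes could not be told: in 15 further probe sets of 11 such genes the change was a median 0.757 of that of the called probe set, with an interval of -0.329 to 1.28. A linked genetic background, carried along with the mutated chromosome from its stock, would put called genes on that chromosome, but the odds ratio is the pattern itself and no separate test of it, and DSas-6, mutated on the same arm, stood at 1.08. A linked background therefore stays open, and the SakOE change of these genes, a median 0.404 of that in DSas-4 and of the same sign in 139, leaves open a chromosome 3 shared by those stocks. The genes were selected against the same wild-type arrays, which by itself can push both values up. No value for unchanged groups was computed.

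Several genes were called in opposite directions in the 2 centrosome-loss mutants. The direct difference, DSas-4 minus DSas-6, was 4.82 for CG31157, 4.50 for CG31287, 4.33 for GILT3, 3.73 for Dred, 3.09 for CG7650, 2.56 for miple1 and 2.37 for CG31495, each with an adjusted p of at most 1.55e-07 (limma). All of these but miple1 were under 4 on all DSas-6 arrays, so that these differences are not sizes of change. For CG31157, CG31287, GILT3 and Dred the wild types were under 4 on all arrays too, and their lower call in DSas-6 compares levels not above background. In total 1744 genes differed between these mutants directly.

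Probe sets with no single gene symbol, left out of the gene comparisons, were called higher 35 times in DSas-4, 46 times in DSas-6 and 45 times in SakOE, and lower 11, 37 and 90 times, among 1095 such probe sets tested.

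The counts were also compared with regroupings of the same arrays. For DSas-4 the real count of 230 was the largest of 100 splits (highest other 166, 1 split as large with the real one included), for DSas-6 429 (highest other 213, 1 split as large) and for SakOE 746 (highest other 280, 1 split as large). For these 3 no other split drawn reached the real count, which argues against a random grouping of the arrays. It does not single out the mutant strain. Other splits mix strains within a group and widen its spread. A difference between the wild types would then favour the real grouping too. Regrouping also mixes the apparent normalization runs, so the splits do not separate strain from run. For SakOE against the loss mutants, 2 of 100 splits were as large as 1769, the highest other at 2305, above the real count. For the genes shared by DSas-4 and DSas-6, 3 of 100 splits reached 15, and the highest other, 197, was several times the real count. In both of these comparisons the splits were not taken as excluding chance, and why some gave larger counts was not tested. For pairs of groups 10 splits exist, too few for a share under 0.05. The real count was the largest, 1 of 10, for w67 against OregonR (1095, highest other 0), DSas-4 against w67 (321, highest other 3), DSas-4 against OregonR (1736, highest other 0), and DSas-6 against w67 (1495, highest other 0). It was also the largest for DSas-6 against OregonR (971, highest other 0), SakOE against w67 (2280, highest other 0), SakOE against OregonR (1269, highest other 0) and DSas-4 against DSas-6 (1744, highest other 0).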

How the results depend on the processing

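With 3 arrays per group, small changes were missed, and in all contrasts but that of DSas-4 with w67 the strain could not be separated from an apparent normalization run. Replicate numbers did not pair the samples as a whole: 2 of 15 arrays were closest to their own number, though w67 and DSas-4 correlated for each number (r = 0.305, 0.183 and 0.121). With the number as a block, DSas-4 gave 204 genes, and 9 named results were lost. In DSas-4 this was Syn (0.44), in DSas-6 sm (0.83) and E2f2. In SakOE the lost calls were Rdl (-0.61), Syn (0.33), wrapper and caup. The shared calls of CG12567 (0.33) and CG1024 (-0.19) were lost too. The cause of the moves below was not tested, except that a fold threshold and genes left out lower a count by construction. With no filter, genes at the lowest value also enter. That value differs between the apparent normalization runs, so results with no filter can include the offset.

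DSas-4 (230 genes) gave 44 with a change of at least 1 log2 unit required, 851 against the mean of the wild types, 30 with chromosome 3 left out, and 159 to 219 with 1 array left out. DSas-6 (429) gave 1168 with no filter, 771 with array weights, 12 with the fold threshold, 1258 against the mean, 240 without chromosome 3 and 253 to 404 with 1 array left out. SakOE (746) gave 1374, 1192, 58, 1917, 274 and 520 to 672 under the same settings. The wild types (1095) gave 4942 with no filter, 538 after quantile normalization, 497 after median centring, 29 with the fold threshold and 606 to 931 with 1 array left out. The genes shared by DSas-4 and DSas-6 (15) were 30 with array weights, 0 with the fold threshold, 7 without chromosome 3 and 9 to 18 with 1 array left out. SakOE against the loss mutants (1769) gave 5526 with no filter, 2916 with array weights, 83 with the fold threshold and 1100 to 1876 with 1 array left out. Lists called in DSas-4 (2) were 0 with the estimated correlation, 2 with fry, where detoxification replaced haemocytes, and 1 to 3 with 1 array left out, in DSas-6 (0) 1 with fry, and in SakOE (0) 1 with fry, 2 after median centring and 7 with no filter. The SAK difference from w67 was -0.18 after median centring and -0.37 to -0.27 with 1 array left out; that from OregonR ran from -0.0355, reversed without OregonR replicate 3, to 0.0725. Of 170 called results of named genes, 21 were lost after quantile normalization and 18 after median centring. With 1 array left out, 53 of these results lost their call at least once, in 258 of 1542 combinations of result and left-out array, and 0 reversed.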

Other observations

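Genes called in SakOE overlapped with those of each centrosome-loss mutant. With DSas-4, 81 genes went the same way and 16 opposite ways, where independent lists would share 12 and 12.6; 72 of the 81 lay on chromosome 3 and 8 elsewhere. Among them Oat, CG14687 and miple1 (3.50-fold in DSas-4 and 2.44-fold in SakOE) rose in both, and CG6912, Cyp4g1, Irc and lncRNA:CR32027 fell in both. Unchanged groups with the same controls shared 0.03 genes on average, but they have hardly any calls to share. With split controls 101 went the same way and 39 opposite ways (29.5 and 28.9 expected), or 173 and 565 (152.2 and 415.5 expected) with the controls exchanged. The latter were 157 and 210 after quantile normalization. With DSas-6, 127 genes went the same way and 18 opposite ways (25.4 and 20.5 for independent lists), 62 of the 127 on chromosome 3; with split controls these were 225 and 124 (142.7 and 129.4 expected), or 244 and 156 (144.0 and 173.5 expected). The overlap of 127 was 83 without DSas-6 replicate 1. After quantile normalization 94 went the same way and 17 opposite ways, and with split controls 168 and 85, or 182 and 115. Over all tested genes the fold changes of DSas-4 and SakOE correlated at r = 0.276 against 0.337 in unchanged groups (covariance 0.0239 against 0.00406). For DSas-6 and SakOE these were 0.237 against 0.341 (covariance 0.0167 against 0.00416).

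In all 3 strains 10 genes were called in the same direction, 7 higher and 3 lower. Among them were Set8, which encodes a histone H4 methyltransferase (1.56-fold, 1.44-fold and 1.51-fold higher in DSas-4, DSas-6 and SakOE), Cyp4e2, Usp10, tay and GNBP2, and the lower genes CG3726, CG1024 and corn. The number expected for unchanged groups sharing these controls was not computed. The DSas-6 call of Cyp4e2 was lost without any 1 array of DSas-6, w67 or OregonR, and the calls of GNBP2, CG12567, CG1024 and corn shared by DSas-4 and DSas-6 were each lost without at least 1 array. The shared call of corn was also lost with the mean of all probe sets of a gene. The amino acid transporter gene path was 3.06-fold higher in SakOE, a fold against OregonR, where replicate 3 stood at 8.81 and the others at 9.98 and 10.3. For path, DSas-4 (10.3 to 10.7) and DSas-6 (9.87 to 10.5) also lay above w67 (7.44 to 7.75). The gene pros, which rose in DSas-6, fell in SakOE.

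In the patterns below all tests were chosen only after the result was seen.

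Of the genes differing between the wild types, 87.8% were higher in w67. Separate normalization of the groups could give such a shift. The 1 pair apparently normalized together, DSas-4 and w67, was 0.00914 apart in its median gene, but the other 9 pairs ran from 0.00817 to 0.118, so the pair did not stand apart. For a true shift of most transcripts, the spike-ins were predicted to be lower in w67. That would follow only if scaling had removed the shift of the genes, which is still present in these values. The 18 spike-in probe sets differed by -0.0513 (exact permutation p = 1, smallest possible 0.1 with 3 arrays per group), which cannot tell. Both stay open.

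In OregonR replicate 3 alone, 50 probe sets stood more than 3 log2 units above all 14 other arrays, led by Peritrophin-15a, which encodes a protein of the gut lining (13.2 against at most 2.18). Gut tissue in that dissection is a likely source: 6 of the 26 gut genes on the array stood more than 1 unit above all others there, among them Jon65Aiv (8.89) and Jon74E (7.83), and 0 in any other array. General noise of that array was argued against, since the SD of its deviations over tested genes was 0.121, within the 0.0939 to 0.192 of the others. Since 1 array cannot pass the filter, these probe sets entered no comparison, and a biological source was not tested.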
